A study of Mus musculus with 26 samples.

How the data were processed

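The samples were 26 mouse 3' RNA-seq libraries amplified from 1 ng of RNA, in 13 sorted groups with 2 replicates each, per the labels' protocols. Groups were d2 PGCLC, intestinal epithelium at E16.5, P3 and P14, retinal photoreceptor precursors at P0, P4 (reporter-positive CD73- and CD73+), P6 and P10, and splenic B cells, blasts, prePB and PB. The blasts, prePB and PB were sorted after 3 days with LPS (10 ng/mL) and IL-4 (2 ng/mL), and the B cells came from spleens of mice aged 8 to 10 weeks, per the labels' protocols. The cells of intestine, retina and spleen came from homozygous EGFP-BLIMP1 knock-in C57BL/6 mice and the PGCLC from a C57BL/6 and 129 line with other reporters, per the labels. The study description calls the P3 and P14 groups embryonic while the sample titles give intestinal epithelium at P3 and P14, and the titles were followed.

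The authors' steps name cutadapt 1.11, TopHat 1.4.1, Bowtie 1.0.1, Cufflinks 2.2.0 and the genome build mm10, per the submitters' processing notes; which step each made, and how reads shared between genes were counted, is not given in the sources used here. The deposited values are an expression signal in RPM as made by the authors, per the file headers. Values below 20.5 reads fell on whole multiples of 1 read (within 0.02 of a read) in 82.7 to 91.3% of cases per library, and in 73.2 to 86.7% with values under 1 read included, so the signal held fractions of reads and was not treated as counts. The smallest step of each library gave its depth, from 1.72 M reads in d2 PGCLC replicate 1 to 6.04 M reads in P14 replicate 2, with 1 read worth 0.583 and 0.166 RPM. Values near 1 RPM therefore rest on a few reads. The deposited values were used without further scaling.

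Of 26310.0 lines, 1164 held values that were moved against the header: 501 gene lines by 1 column and 513 by 2 columns to the left, 92 lines of ERCC spike-ins by 3 columns to the left, 54 gene lines by 1 and 4 by 2 columns to the right. This was tested by the share of values that were whole reads after each possible move. The best move made 23.0% of low values whole for the 501 lines moved by 1 column, where other moves reached at most 5.97%, so their position is less certain, as are the immunoglobulin values in them. It made 89.3, 91.1 and 83.3% whole for the 513, 54 and 4 gene lines. The 1072 gene lines among them (4.09% of gene lines), which hold most immunoglobulin genes, were left out of all comparisons, and 25146 lines were used. The share of reads left to other genes was their RPM sum over the lines used. Immunoglobulin values of the closing part came from lines set back under the header, where d2 PGCLC replicate 1 has no value. Spike-in lines were not used. Entrez IDs and positions came from the RefSeq annotation of GRCm38.p6, in which 24619 IDs were matched.

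Tests ran in R 4.3.3 with limma 3.58.1; tables and figures were made in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Values were taken as log2(RPM + 1), and genes with at least 5 RPM in at least 2 samples of a fit were tested. Each lineage had its own limma-trend fit (8 samples of the B lineage, 6 of the intestine, 10 of the retina), and the 4 reporter-positive lineages a further fit of 8 samples. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05 with an absolute log2 fold change of at least 1. A gene was enriched in a lineage when the largest p of its 3 comparisons, adjusted, and each of the 3 fold changes passed. Opposite changes between lineages were tested as a difference in a limma fit of all 26 samples.

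The 35 gene lists were written before the data were examined: B cell identity, MHC class II presentation, plasma cell program, genes known to be repressed by BLIMP1 in B cells, ER protein folding and secretion, cell cycle, glycolysis, T cell, NK cell and myeloid markers, erythroid markers, enterocyte absorption and brush border, suckling-period enterocyte, adult-type enterocyte, MHC class I and interferon response, intestinal stem cell and crypt, goblet cell, enteroendocrine cell, Paneth cell and antimicrobial, fetal growth and imprinted genes, mesenchyme, endothelium and enteric neuron markers, immediate early and dissociation stress, rod phototransduction and outer segment, photoreceptor transcription factors, cone photoreceptor, photoreceptor ribbon synapse, cilium and intraflagellar transport, retinal progenitor and neurogenic, bipolar cell, Muller glia, amacrine, horizontal and ganglion cell, endothelial and pericyte markers, PGC specification, naive pluripotency, primed epiblast and DNA methylation, mesoderm and BMP response, and later germ cell. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and also with an estimated correlation and with fry, adjusted by Benjamini-Hochberg within each lineage. Of 277 tests, 165 passed with the preset correlation, 17 with an estimated correlation and 203 with fry. Lists are written as called or not called by camera with the preset correlation, unless fry is named. Erythroid and endothelial markers had under 5 tested members in every fit, as had later germ cell genes.

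Genes were named by a rule written before the data were examined. It takes the 8 largest called rises and falls per comparison (5 for comparisons of both ends of a series) whose groups do not overlap and whose higher group has at least 20 RPM. It adds up to 4 called members per list, 10 genes per enriched set, 4 per overlap direction, and always Prdm1, Nt5e, Sdc1, Epcam and Ptprc. Gene models without names, small RNA genes and immunoglobulin segments were left out of the ranked parts, the latter because counting could split their reads. Where all libraries of the lower group were at 0, the RPM is given without a fold change. Some genes that met the rule are not reported here.

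The steps were tested on simulated data in which 200 genes per comparison had known changes. At 2, 3 and 6 fold the shares recovered were 46.3, 95.5 and 100% for Blast against B cell (9508 genes, 6 false calls), 46.3, 95.5 and 100% for prePB against Blast (9519 genes, 4 false calls), 43.3, 95.5 and 98.5% for PB against prePB (9523 genes, 4 false calls) and 37.3, 98.5 and 100% for PB against Blast (9515 genes, 4 false calls). In the intestine they were 44.8, 100 and 100% for P3 against E16.5 (10311 genes, 3 false calls), 40.3, 94.0 and 100% for P14 against P3 (10359 genes, 3 false calls) and 44.8, 92.5 and 97.0% for P14 against E16.5 (10358 genes, 3 false calls). In the retina they were 50.8, 92.5 and 100% for P4 GFP+ CD73- against P0 (11423 genes, 2 false calls), 52.2, 92.5 and 100% for P4 CD73+ against P4 GFP+ CD73- (11418 genes, 1 false call), 37.3, 94.0 and 100% for P6 against P4 CD73+ (11431 genes, 4 false calls), 41.8, 98.5 and 100% for P10 against P6 (11443 genes, 4 false calls) and 43.3, 100 and 100% for P10 against P0 (11429 genes, 2 false calls). For enrichment they were 14.7, 93.9 and 100% for PGCLC (11737 genes) and 5.88, 97.0 and 100% for E16.5 (11710 genes). They were 20.6, 100 and 100% for P0 (11695 genes) and 23.5, 93.9 and 100% for PB (11708 genes), all 4 with 0 false calls. A changed list of ER genes was recovered in a comparison of each of the 3 lineages by camera with either correlation and by fry, and fry called 2 other lists in the intestine. Genes were simulated independently, so list tests were not tried under correlation between genes. At 2 fold, recovery was limited by the minimum fold change. False calls under a general shift, as from Blast to PB, were not tried. The overlap step recovered 200 of 200 shared genes among 8353.

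Alternatives set before the data were examined were pseudocounts of 0.5 and 5 RPM, a filter at 20 RPM or none, median-of-ratios and quantile scaling, no minimum fold change, 1 fit of all samples, a term for the replicate number, other stages in place of PB, P0, P14 and P10, and each replicate left out in turn. Setting the moved lines back was added after the data were seen.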

Results

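Expression was compared across 4 mouse lineages that turn on the transcriptional repressor BLIMP1, encoded by Prdm1: germ cells induced in culture, intestinal epithelium, retinal photoreceptor precursors and B cells on the way to plasmablasts. The 26 libraries came from 13 sorted groups (n = 2 per group). Cells of the intestine, retina and spleen carried an EGFP-BLIMP1 reporter on both alleles, and the day 2 germ cell-like cells (PGCLC) came from another reporter line. No label states that replicates came from separate animals or cultures, so the p-values measure only the spread between these samples. Values are mean ± SD in RPM, and changes are log2 fold changes ± standard error from limma, with p-values adjusted by Benjamini-Hochberg. A change was called, written as rose or fell, when it passed the adjusted threshold and a log2 fold change of at least 1.

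Prdm1 (Entrez ID 12142; chromosome 10, 44437174 to 44528558, GRCm38.p6) was higher in the reporter-positive than in the reporter-negative cells of the B-lineage cultures. It stood at 9.83 ± 0.961 RPM in splenic B cells, 2.81 ± 0.699 in reporter-negative blasts, 145 ± 13.7 in reporter-positive CD138- cells (prePB) and 212 ± 42.6 in reporter-positive CD138+ plasmablasts (PB). In intestinal epithelium it was 100.5 ± 9.87 RPM at E16.5, 58.8 ± 17.8 at P3 and 19.1 ± 3.16 at P14. In retinal precursors it was 484 ± 3.75 RPM at P0 and 499 ± 4.52 in the CD73- sort at P4, then 281 ± 9.16, 155 ± 12.5 and 83.2 ± 3.93 in the CD73+ sorts at P4, P6 and P10. PGCLC had 26.5 ± 2.88 RPM.

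The genes of the sorting markers were compared with the gates. Sdc1, which encodes CD138 (Entrez ID 20969; chromosome 12, 8771396 to 8793716), stood at 9.53 ± 0.556 RPM in PB against 0.150 ± 0.212 in prePB and was listed at 0 in Blast. Without a gate on CD138, the intestine held 10.2 ± 1.34, 14.6 ± 0.325 and 13.1 ± 4.29 RPM of Sdc1 at E16.5, P3 and P14. Nt5e, which encodes CD73 (Entrez ID 23959; chromosome 9, 88327609 to 88372089), rose in the retina from 13.3 ± 6.93 RPM at P0 to 396 ± 0.559 at P10. The CD73- sort at P4 also held 117 ± 39.2 RPM of Nt5e, against 274 ± 69.7 in the CD73+ sort. Epcam, an epithelial adhesion gene (Entrez ID 17075; chromosome 17, 87635979 to 87651127), was 787 ± 99.7, 1047 ± 6.35 and 950.1 ± 194 RPM at the 3 intestinal ages and 156 ± 11.6 in PGCLC. Ptprc, the common leukocyte antigen behind B220 (Entrez ID 19264; chromosome 1, 138062859 to 138175756), was 1095 ± 5.36 RPM in B cells and 228 ± 36.4, 242 ± 26.6 and 247 ± 16.2 in the 3 cultured groups, and its highest mean elsewhere was 2.31 ± 1.24.

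**Figure D1:**
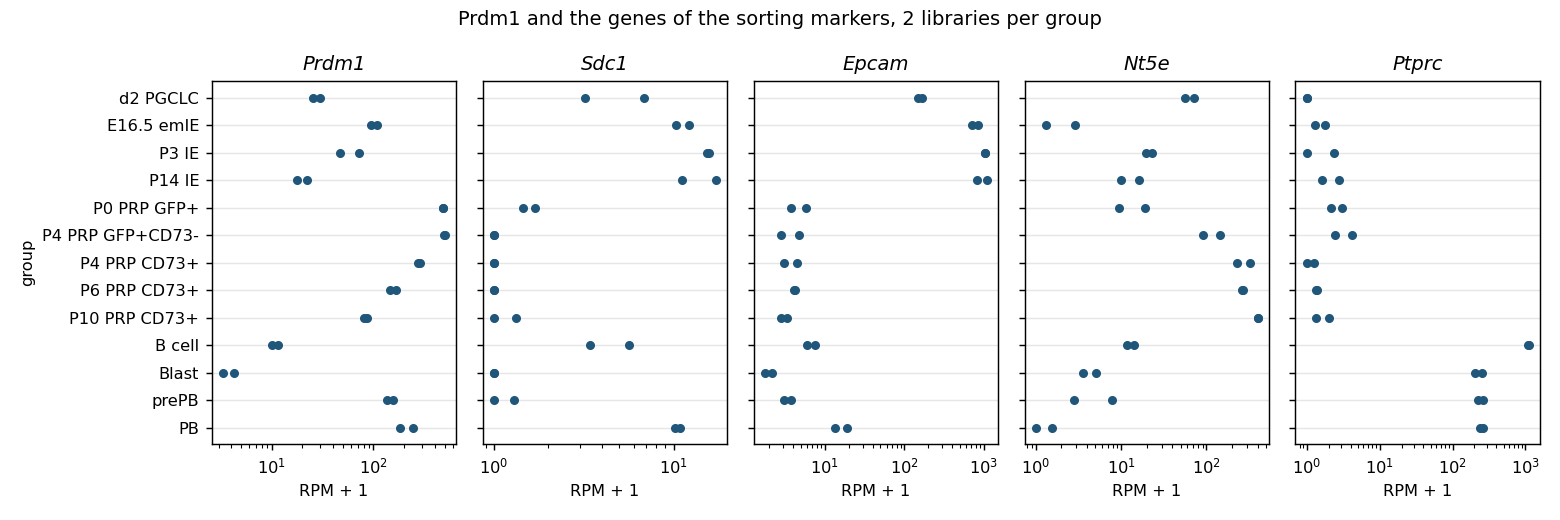
Prdm1 and the genes of the sorting markers in each library. Each dot is 1 library, on a log axis of RPM plus 1.

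Blasts that had not turned on the reporter after 3 days with LPS and IL-4 differed from splenic B cells by a proliferative and metabolic program. Genes of B cell identity, genes of plasma cells and markers of T, NK and myeloid cells were lower. Ccl22 (218 ± 95.6 against 0.828 ± 0.830 RPM, log2 6.91 ± 0.40), a chemokine (Entrez ID 20299; chromosome 8, 94745684 to 94751388), rose together with Lad1 (147 ± 33.4 against 0.602 ± 0.852 RPM, log2 6.63 ± 0.39), a basement membrane filament gene, and Nfil3 (189 ± 42.5 against 2.76 ± 1.52 RPM, log2 5.70 ± 0.30), a transcription factor of IL-4 signalling. The other large rises were Tmem176b (5.52 ± 0.17), Gbp1 (5.49 ± 0.37), an interferon-induced GTPase, Timd2 (4.88 ± 0.25), Fabp5 (4.83 ± 0.26), a fatty acid carrier, and Htr7 (47.7 ± 0.352 RPM in Blast, listed at 0 in B cell). Igj, which encodes the J chain of secreted IgM (Entrez ID 16069; chromosome 5, 88519809 to 88527897), fell from 1758 ± 94.3 to 9.80 ± 7.32 RPM (log2 -7.54 ± 0.32). Acp5 (-7.14 ± 0.32), Dock2 (-6.44 ± 1.03), Fcrla (-6.25 ± 0.27), S1pr1 (-5.82 ± 0.39), the receptor for exit from lymphoid organs, and Abca1 (-5.81 ± 0.38) fell too, as did Tyrobp (247 ± 58.8 RPM in B cell, listed at 0 in Blast). The highest adjusted p of these 15 was 1.3e-04.

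Cell cycle genes rose in 31 of 37 tested members (median 1.60, adjusted p = 5.6e-18, 0.055 with an estimated correlation), among them Cdc6 (2.88 ± 0.32), Tyms (2.64 ± 0.19) and Ccnb1 (2.56 ± 0.23). Glycolysis genes rose in 8 of 15 (adjusted p = 5.5e-06, 0.065 with an estimated correlation), led by Hk2 (2.30 ± 0.39) and Gapdh (1.81 ± 0.20). The list of ER protein folding and secretion moved up (8 of 38 rose and 3 fell; adjusted p = 9.1e-04, 0.19 with an estimated correlation), with Sdf2l1 (2.15 ± 0.20) up and Ero1lb (-2.44 ± 0.18) down. B cell identity genes fell in 15 of 24 (median -1.77, adjusted p = 4.7e-08, 0.055 with an estimated correlation), including the complement receptor Cr2 (-5.75 ± 0.41), Faim3 (-4.81 ± 0.17) and Bank1 (-4.00 ± 0.25). Plasma cell genes were also lower in blasts, with 10 of 19 down and 1 up (adjusted p = 0.0055, 0.13 with an estimated correlation), and 3 of 11 genes of MHC class II presentation fell (adjusted p = 0.0047, 0.097 with an estimated correlation).

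Markers of T cells, NK cells and myeloid cells fell in 12 of 15 (13 adjusted over the list alone; adjusted p = 1.0e-05, 0.064 with an estimated correlation), for example Fcer1g (-4.07 ± 0.42) and Nkg7 (-3.99 ± 0.54); these genes moved with the B220+ spleen sort. Among genes known to be repressed by BLIMP1, 2 of 7 rose and 3 fell, including Bcl6 (-2.53 ± 0.43) and Spib (-1.84 ± 0.20) among the falls, and the list as a whole was not called (adjusted p = 0.47). Neither the immediate early list (adjusted p = 0.077) nor the MHC class I and interferon list (adjusted p = 0.88; median and mean just below 0, test up) was called. The interferon list held Gbp2 (4.74 ± 0.23) and Ifit3 (-4.60 ± 0.51) in opposite directions. Prdm1 itself fell by 1.52 ± 0.24 (adjusted p = 1.0e-04). In all, 1218 genes rose and 2149 fell among 9871, while the median gene moved by -0.18. Rises made up 36.2% of the calls, and 51.0% with quantile normalization.

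Gain of the reporter at the same time of culture (prePB against Blast) came with the secretory program. Igj (2002 ± 4.36 against 9.80 ± 7.32 RPM, log2 7.72 ± 0.32) rose most, then Prdm1 (145 ± 13.7 against 2.81 ± 0.699 RPM, log2 5.27 ± 0.24) and Cd24a (851 ± 13.6 against 31.8 ± 10.3 RPM, log2 4.73 ± 0.19), a surface sialoglycoprotein. Il10 (22.8 ± 4.20 against 0.144 ± 0.204 RPM, log2 4.38 ± 0.46), a cytokine of regulatory B cells, Bhlha15 (4.25 ± 0.32), a transcription factor of secretory cells, Ly6c2 (4.21 ± 0.22), Sec24d (3.91 ± 0.28), a coat protein of ER export, and Prg2 (3.82 ± 0.38) also rose. The glycosyltransferase B3gnt5 (1.83 ± 2.59 against 55.9 ± 0.234 RPM, log2 -4.72 ± 0.51) fell most. Lta (-3.71 ± 0.48), which encodes lymphotoxin alpha, Grm6 (-3.71 ± 0.44), Treml2 (-3.67 ± 0.31), Parp3 (-3.61 ± 0.33), Lmo2 (-3.55 ± 0.43), Gbp2 (-3.54 ± 0.23) and Plbd1 (-3.40 ± 0.30) fell as well. The largest adjusted p among these 16 was 1.0e-04.

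The plasma cell program rose in 16 of 19 members (median 2.23, adjusted p = 9.4e-33, 0.007 with an estimated correlation), including Fam46c (3.35 ± 0.20). ER folding and secretion rose in 21 of 38 (median 1.03, adjusted p = 5.8e-34, 0.015 with an estimated correlation), including Ero1lb (2.81 ± 0.18), Edem1 (2.35 ± 0.15) and Dnajb9 (2.05 ± 0.16). Genes known to be repressed by BLIMP1 fell in 5 of 7 (median -1.98, adjusted p = 7.1e-06, 0.038 with an estimated correlation): Spib (-3.25 ± 0.20), Pax5 (-2.09 ± 0.23) and Bcl6 (-1.98 ± 0.43) were among them. B cell identity genes fell in 10 of 24 (11 adjusted over the list alone), with Fcer2a (-2.72 ± 0.22) among them, and 1 rose (adjusted p = 0.02, 0.27 with an estimated correlation). The immediate early list moved up (adjusted p = 0.011, 0.19 with an estimated correlation, 0.42 by fry) although 2 members rose and 2 fell. Lists of cell cycle, glycolysis, MHC class II, MHC class I and T, NK and myeloid genes were not called (adjusted p from 0.081 to 0.89); for MHC class I the mean lay below 0 and the median above, and for T, NK and myeloid genes both lay below 0 while the test pointed up.

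CD138+ plasmablasts extended this program over prePB. Igj (13123 ± 449.6 against 2002 ± 4.36 RPM, log2 2.71 ± 0.32) rose again, with Cacna1h (23.3 ± 7.49 against 2.73 ± 0.891 RPM, log2 2.69 ± 0.39), a calcium channel, and Slpi (88.5 ± 10.4 against 15.0 ± 2.59 RPM, log2 2.49 ± 0.42), a protease inhibitor. Pik3cg (2.24 ± 0.23), Ly6c2 (1.99 ± 0.22), Pon3 (1.93 ± 0.21), Trp53inp1 (1.91 ± 0.17) and Oosp1 (1.90 ± 0.39) followed. Oosp1 was not called without PB replicate 2 (1.29). Sdc1 (9.53 ± 0.556 against 0.150 ± 0.212 RPM, log2 3.21 ± 0.42) rose with its gate, and so did Epcam (15.4 ± 3.88 against 2.42 ± 0.459 RPM, log2 2.25 ± 0.38). Ccl22 (5.66 ± 3.59 against 137 ± 4.44 RPM, log2 -4.48 ± 0.40) fell most, followed by Ciita (-4.21 ± 0.30), the MHC class II transactivator, Dnase1l3 (-3.79 ± 0.33), Cd22 (-3.55 ± 0.39), a brake on the B-cell receptor, Fas (-3.24 ± 0.31), a death receptor, Ms4a6c (-3.19 ± 0.50), Lcp2 (-3.07 ± 0.30) and Serpinb6b (-3.07 ± 0.27). The change of Prdm1 was not called (0.53 ± 0.24, adjusted p = 0.11).

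Plasma cell genes rose in 11 of 19 (median 1.09, adjusted p = 3.7e-29, 0.007 with an estimated correlation), including Tnfrsf17 (7.45 ± 1.89 RPM in PB, listed at 0 in prePB), the BCMA receptor. Only 3 of 38 ER genes passed the threshold singly, Edem1 (1.28 ± 0.15), Edem2 (1.27 ± 0.20) and Sel1l (1.13 ± 0.17), yet the list moved up (adjusted p = 1.1e-20, 0.028 with an estimated correlation). MHC class II presentation fell in 8 of 11 (median -1.35, adjusted p = 7.2e-08, 0.028 with an estimated correlation), with H2-Oa (-2.70 ± 0.18) and H2-DMb2 (-2.23 ± 0.22). Genes known to be repressed by BLIMP1 fell in 6 of 7 (median -2.27, adjusted p = 9.4e-06, 0.038 with an estimated correlation), with Id3 (-2.85 ± 0.23). B cell identity fell in 12 of 24 (adjusted p = 3.5e-05, 0.1 with an estimated correlation), with Ccr7 (-2.55 ± 0.37). Glycolysis genes fell in 3 of 15 (adjusted p = 0.0019, 0.15 with an estimated correlation), with Gpi1 (-1.14 ± 0.16). The cell cycle, T, NK and myeloid, MHC class I and immediate early lists were not called (adjusted p from 0.11 to 0.8); the medians of all 4 were below 0 while the test pointed up.

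Across both steps (PB against Blast), Igj (13123 ± 449.6 against 9.80 ± 7.32 RPM, log2 10.43 ± 0.32), Ly6c2 (6.20 ± 0.22), Prdm1 (5.80 ± 0.24), Pon3 (5.44 ± 0.21) and Cd24a (5.30 ± 0.19) rose most. Gbp2 (-5.62 ± 0.23), Spib (-5.52 ± 0.20), Cd22 (-5.43 ± 0.39), Treml2 (-5.31 ± 0.31) and Ciita (-5.24 ± 0.30) fell most (largest adjusted p of the 10: 6.2e-08). The plasma cell program rose in 18 of 19 (median 3.47, adjusted p = 6.2e-35, 0.007 with an estimated correlation). ER folding and secretion rose in 31 of 38 (median 1.49, adjusted p = 1.0e-34, 0.015 with an estimated correlation), with Edem1 (3.63 ± 0.15). All 7 genes known to be repressed by BLIMP1 fell (median -3.75, adjusted p = 2.2e-05, 0.04 with an estimated correlation), among them Pax5 (-3.75 ± 0.23). MHC class II fell in 9 of 11 (adjusted p = 2.2e-04, 0.055 with an estimated correlation). B cell identity genes fell in 15 of 24, with 3 up (adjusted p = 0.0031, 0.19 with an estimated correlation). Glycolysis genes fell in 5 of 15 (adjusted p = 0.044, 0.28 with an estimated correlation, 0.16 with median-of-ratios scaling, 0.061 with quantile normalization). The immediate early list moved up with 4 rises and 3 falls (adjusted p = 0.0071, 0.19 with an estimated correlation, 0.88 by fry), and 2 of those rises, Fos (2.21) and Egr1 (0.916), were not called without PB replicate 1, nor Egr1 (1.32) without Blast replicate 2.

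The share of reads left to genes other than immunoglobulins fell by 0.54 log2 from Blast to PB, and the median gene moved by -0.24 from Blast to prePB, -0.39 from prePB to PB and -0.64 from Blast to PB. Counts of rises and falls changed with scaling. From Blast to prePB 437 genes rose and 575 fell, and 568 and 329 with median-of-ratios scaling. From prePB to PB 124 rose and 1157 fell, against 398 and 407 after scaling. From Blast to PB the counts were 657 and 3051, against 1271 and 1113. Of the 7 called lists, 6 were still called in the same direction. Medians after scaling from Blast to PB were 4.13 for the plasma cell program, 2.15 for ER folding, -3.13 for genes repressed by BLIMP1, -0.81 for MHC class II and -1.62 for B cell identity. The immediate early list stayed called too (adjusted p = 0.029 after scaling), but glycolysis did not (0.16 after scaling, median -0.24). The cell cycle median changed sign with scaling, from -0.27 to 0.38. It was not called with the values as deposited (adjusted p = 0.57) and was called up after scaling (0.031, and 0.0096 from prePB to PB). Quantile normalization gave no call (0.094 and 0.058). As deposited, fry called the list down from Blast to PB (0.035). However, fry tests a list against no change and camera against the other genes, and the median of all genes was -0.64. The direction of the cell cycle list was left open. Neither the T, NK and myeloid (adjusted p = 0.61) nor the MHC class I list (adjusted p = 0.19) was called as deposited.

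**Figure D2:**
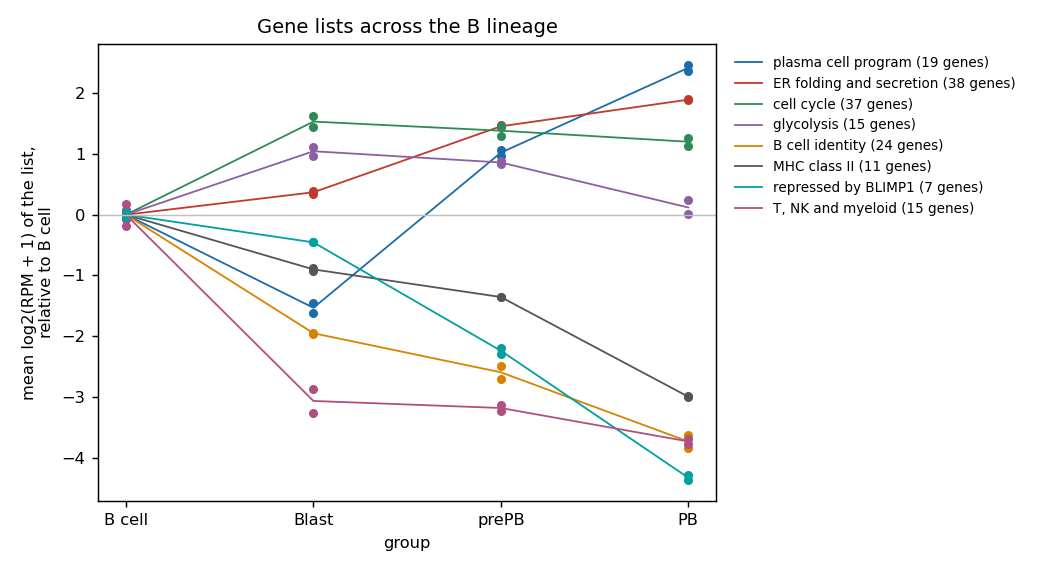
Mean log2(RPM + 1) of gene lists in the B lineage, relative to splenic B cells. Each dot is 1 library and lines join group means.

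In the intestine, age and gate changed together: the E16.5 cells were reporter-positive EpCAM+ and the P3 and P14 cells reporter-negative EpCAM+, per the labels' protocols. From E16.5 to P3, genes of secretory and crypt cells rose and enterocyte genes fell. Sst (955 ± 298 against 4.70 ± 3.39 RPM, log2 7.49 ± 0.32) and Gip (1596 ± 405 against 11.3 ± 10.7 RPM, log2 7.34 ± 0.37), hormones of enteroendocrine cells, Cym (3236 ± 275 against 17.6 ± 3.45 RPM, log2 7.46 ± 0.19), the milk-clotting protease chymosin, and Olfm4 (1829 ± 189 against 16.3 ± 0.836 RPM, log2 6.72 ± 0.16), a crypt stem cell gene (Entrez ID 380924; chromosome 14, 80000302 to 80023141), were among the largest rises. Nts (7.15 ± 0.40), Chga (6.69 ± 0.25), Pyy (6.38 ± 0.27) and the potassium channel Kcnn4 (6.01 ± 0.29) completed the 8. Scd2 (1.12 ± 0.318 against 641 ± 31.6 RPM, log2 -8.25 ± 0.28), a lipid desaturase, and the imprinted H19 (74.3 ± 14.7 against 6937 ± 47.7 RPM, log2 -6.54 ± 0.23) (Entrez ID 14955; chromosome 7, 142575530 to 142578146) and Igf2 (75.0 ± 0.134 against 3956 ± 433 RPM, log2 -5.70 ± 0.17) (Entrez ID 16002; chromosome 7, 142650768 to 142666816) fell most. Bcl2l15 (-6.02 ± 0.33), Igf2as (-5.61 ± 0.42), Gsta1 (-5.40 ± 0.40), Klhl2 (44.4 ± 4.02 RPM in E16.5, listed at 0 in P3) and Abca13 (36.8 ± 4.22 RPM in E16.5, listed at 0 in P3) fell too. All 16 had an adjusted p of at most 8.2e-09.

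All 17 enteroendocrine genes rose (median 4.30, adjusted p = 3.6e-21, 0.078 with an estimated correlation). Stem cell and crypt genes rose in 14 of 15 (adjusted p = 1.2e-14, 0.048 with an estimated correlation), with Lgr5 (4.19 ± 0.28) and Ascl2 (4.05 ± 0.27). Goblet genes rose in 7 of 11 (adjusted p = 2.4e-07, 0.078 with an estimated correlation), with Muc2 (3.19 ± 0.20) and Spink4 (3.44 ± 0.19). Paneth and antimicrobial genes rose in 9 of 13 and fell in 2 (adjusted p = 5.3e-06, 0.18 with an estimated correlation), with Defa24 (5.36 ± 0.16) and Mmp7 (4.51 ± 0.35). Cell cycle genes rose in 28 of 37 (adjusted p = 3.2e-17, 0.078 with an estimated correlation), with Cdc6 (2.26 ± 0.38) and Mcm3 (2.02 ± 0.18). MHC class I and interferon genes rose in 9 of 13 (adjusted p = 6.2e-04, 0.26 with an estimated correlation), with the immunoproteasome gene Psmb8 (3.57 ± 0.31). Immediate early genes of dissociation stress rose in 15 of 20 (adjusted p = 4.7e-12, 0.048 with an estimated correlation), with Fosb (3.32 ± 0.20) and Dusp1 (3.14 ± 0.36), and so moved with the same groups.

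Enterocyte genes fell in 16 of 27 (median -1.10, adjusted p = 4.9e-14, 0.061 with an estimated correlation), with Enpep (-4.79 ± 0.24), a brush border peptidase, and Fabp1 (-2.18 ± 0.14). Genes of the suckling-period enterocyte fell in 9 of 12 (adjusted p = 4.7e-12, 0.061 with an estimated correlation), with the uptake receptor Cubn (-4.91 ± 0.29) and Ass1 (-4.28 ± 0.25), an enzyme of arginine synthesis. Glycolysis genes fell in 11 of 14 (adjusted p = 1.8e-13, 0.048 with an estimated correlation), with Aldoc (-2.61 ± 0.42) and the glucose transporter Slc2a1 (-2.33 ± 0.41). Fetal and imprinted genes fell in 6 of 12 (adjusted p = 2.9e-08, 0.061 with an estimated correlation), with Cdkn1c (-4.99 ± 0.19). ER folding genes fell in 9 of 38 (adjusted p = 1.9e-08, 0.18 with an estimated correlation), with Hspa5 (-1.37 ± 0.13). The lists of adult-type enterocytes (adjusted p = 0.73) and MHC class II (adjusted p = 0.75; median -0.30, mean above 0) were not called, although Sis (4.20 ± 0.37), the disaccharidase of adult gut, rose; in the adult-type list 2 of 7 rose and 1 fell. In total 1321 genes rose and 859 fell among 10481, with a median shift of 0.11. Rises were 60.6% of the calls and 49.6% with quantile normalization. Prdm1 stayed under the minimum fold change (-0.79 ± 0.22, adjusted p = 0.0077).

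From P3 to P14, with the gate unchanged, antimicrobial genes rose and fetal genes continued to fall. Defa5 (89.0 ± 28.3 against 0.613 ± 0.122 RPM, log2 5.77 ± 0.44), a Paneth cell defensin, Zg16 (254 ± 172 against 10.0 ± 2.29 RPM, log2 4.36 ± 0.36), a goblet cell lectin, and Pla2g2a (123 ± 154 RPM in P14, listed at 0 in P3), a bactericidal phospholipase, were the largest rises, the latter 2 with a wide spread between libraries. Defa20 (3.99 ± 0.37), Fabp6 (3.69 ± 0.59), a bile acid carrier of the ileum, Pkp1 (3.58 ± 0.47) and Reg3a (3.45 ± 0.43) followed. Reads of the defensin and Reg families can be shared between paralogs, so single members are uncertain. H19 (1.79 ± 1.36 against 74.3 ± 14.7 RPM, log2 -4.83 ± 0.23) and Igf2 (5.27 ± 0.978 against 75.0 ± 0.134 RPM, log2 -3.61 ± 0.17) fell most, then Cartpt (-3.09 ± 0.48), Cym (-2.87 ± 0.19), Nts (-2.80 ± 0.40), Capg (-2.65 ± 0.34) and Ptprt (-2.62 ± 0.33). These 14 genes had an adjusted p of at most 1.7e-04.

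Paneth and antimicrobial genes rose in 9 of 13 with 1 down (adjusted p = 4.8e-16, 0.066 with an estimated correlation), including the lysozyme Lyz1 (3.21 ± 0.26). Goblet genes rose in 3 of 11 (adjusted p = 1.1e-10, 0.061 with an estimated correlation). Enterocyte genes fell in 14 of 27 (15 adjusted over the list alone; median -1.03, adjusted p = 1.3e-12, 0.061 with an estimated correlation), with Apoa4 (-2.02 ± 0.13), Cd36 (-1.99 ± 0.38) and Fabp2 (-1.56 ± 0.13) down and Enpep (2.31 ± 0.24) up. Enteroendocrine genes fell in 8 of 17 (adjusted p = 1.8e-04, 0.36 with an estimated correlation, 0.32 by fry), with Sst (-2.40 ± 0.32) and Pyy (-2.12 ± 0.27). Fetal and imprinted genes fell in 6 of 12 (8 adjusted over the list alone; adjusted p = 1.2e-13, 0.057 with an estimated correlation). The MHC class I list fell (adjusted p = 5.8e-04, 0.26 with an estimated correlation) with 3 of 13 members called, and the immediate early list moved up (adjusted p = 1.2e-05, 0.061 with an estimated correlation) with 1 member called. The cell cycle list moved down (adjusted p = 0.036, 0.56 with an estimated correlation, 0.12 by fry, 0.06 with median-of-ratios scaling) with none of 37 members called by limma. Lists of stem cell and crypt, suckling-period and adult-type enterocyte, ER folding, glycolysis and MHC class II genes were not called (adjusted p from 0.25 to 0.94; mean, median and test differed in sign for ER, stem cell, glycolysis and MHC class II genes), though Arg2 (3.40 ± 0.52), an adult-type enterocyte gene, rose. Prdm1 fell (-1.55 ± 0.22, adjusted p = 5.5e-05). The 209 rises and 252 falls numbered 461 together, and 269 without P3 replicate 1, 283 without P3 replicate 2 and 278 without P14 replicate 1.

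Over the whole intestinal series (P14 against E16.5), Itln1 (139 ± 46.9 RPM in P14, listed at 0 in E16.5), Olfm4 (6.90 ± 0.16), Defa20 (6.73 ± 0.37), Chga (6.63 ± 0.25) and Defa-rs7 (6.55 ± 0.22) rose most. H19 (-11.37 ± 0.23), Igf2 (-9.31 ± 0.17), Cdkn1c (-6.49 ± 0.19), Igf2as (-6.21 ± 0.42) and Scd2 (-5.56 ± 0.28) fell most (largest adjusted p of the 10: 2.6e-11). Enterocyte genes fell in 23 of 27 (median -1.97, adjusted p = 3.6e-21, 0.057 with an estimated correlation), with Fabp1 (-3.23 ± 0.14) and Apoa1 (-3.07 ± 0.15). Suckling-period genes fell in 11 of 12 (adjusted p = 1.3e-12, 0.061 with an estimated correlation). Fetal genes fell in 11 of 12 (adjusted p = 2.7e-12, 0.061 with an estimated correlation). Glycolysis genes fell in 11 of 14 (adjusted p = 1.3e-11, 0.048 with an estimated correlation). ER folding genes fell in 8 of 38 (adjusted p = 2.4e-06, 0.23 with an estimated correlation). Rises reached 17 of 17 enteroendocrine genes (adjusted p = 3.1e-18, 0.087 with an estimated correlation). They also reached 13 of 15 stem cell and crypt (adjusted p = 4.9e-14, 0.048 with an estimated correlation), 9 of 11 goblet (adjusted p = 7.7e-13, 0.061 with an estimated correlation) and 10 of 13 (11 adjusted over the list alone) Paneth genes, with 1 Paneth gene down (adjusted p = 2.8e-12, 0.083 with an estimated correlation). Cell cycle genes rose in 23 of 37 (adjusted p = 1.8e-13, 0.09 with an estimated correlation). Immediate early genes rose in 14 of 20 (adjusted p = 4.9e-14, 0.048 with an estimated correlation). MHC class I, MHC class II and adult-type enterocyte lists were not called (adjusted p from 0.063 to 0.65), while Sis (4.75 ± 0.37), Arg2 (3.29 ± 0.52) and the trehalose enzyme Treh (2.49 ± 0.46) were among 4 rises in the adult-type list, against 2 falls, of 7. Counts were 1240 up and 1095 down, with Prdm1 among the falls (-2.34 ± 0.22).

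**Figure D3:**
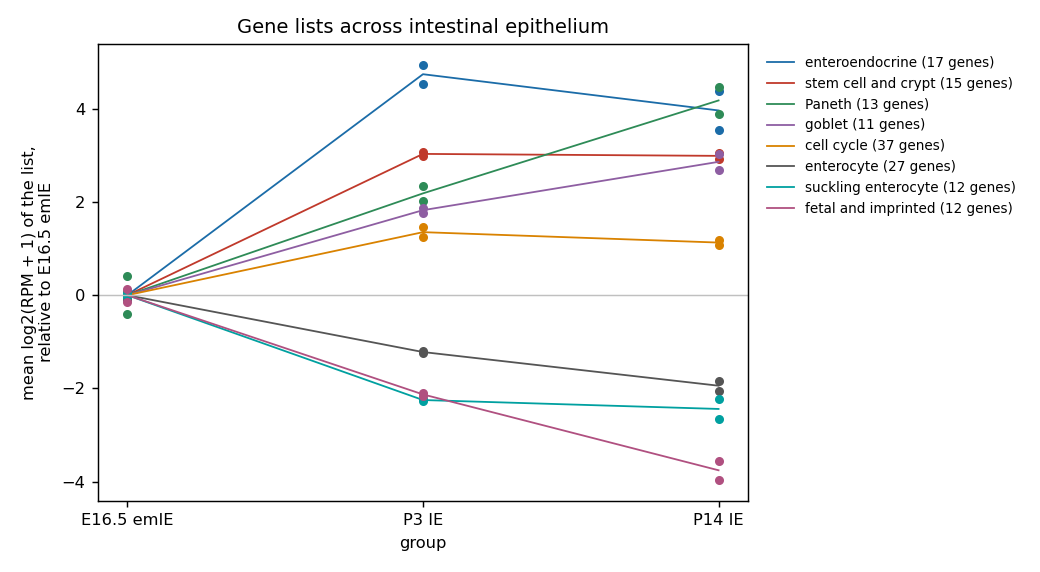
Mean log2(RPM + 1) of gene lists in intestinal epithelium, relative to E16.5. Each dot is 1 library and lines join group means.

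In the retina, reporter-positive precursors that were CD73- at P4 differed from those at P0 by gain of rod genes and loss of neurogenic genes; the CD73 gate differed too. Pde6b (179.7 ± 36.4 against 4.23 ± 1.70 RPM, log2 5.13 ± 0.21), Cnga1 (38.2 ± 3.76 against 1.27 ± 0.837 RPM, log2 4.16 ± 0.21) and Sag (358 ± 7.41 against 28.8 ± 12.3 RPM, log2 3.65 ± 0.21) of the phototransduction cascade and the rod transcription factor Nr2e3 (276 ± 28.9 against 14.8 ± 3.43 RPM, log2 4.15 ± 0.16) rose. Pitpnm3 (3.94 ± 0.14), Cngb1 (3.94 ± 0.15), Tmem91 (3.67 ± 0.42) and Pcdhga10 (4.30 ± 0.73), of a protocadherin cluster whose members share exons, rose as well. Sstr2 (4.86 ± 3.21 against 119.5 ± 7.95 RPM, log2 -4.48 ± 0.47), the somatostatin receptor, Atoh7 (17.0 ± 6.40 against 289.7 ± 29.3 RPM, log2 -4.05 ± 0.34) and Neurog2 (50.8 ± 26.6 against 528 ± 0.544 RPM, log2 -3.45 ± 0.29), proneural factors, fell. So did Pcdh17 (-4.27 ± 0.36), Ptpru (-3.54 ± 0.48), Cdca5 (-3.38 ± 0.45), Pkib (-3.36 ± 0.38) and E2f8 (-3.34 ± 0.57). The highest adjusted p of these 16 was 6.5e-04.

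Rod genes rose in 26 of 30 (median 2.28, adjusted p = 1.4e-31, 0.089 with an estimated correlation). Ribbon synapse genes rose in 10 of 16 (adjusted p = 1.0e-12, 0.12 with an estimated correlation), with Cacna2d4 (2.19 ± 0.23) and the glutamate transporter Slc17a7 (1.94 ± 0.25). Cilium genes rose in 6 of 30 (adjusted p = 7.4e-06, 0.2 with an estimated correlation), with Rpgrip1 (2.03 ± 0.26). Photoreceptor transcription factors rose in 5 of 11 (adjusted p = 1.0e-07, 0.14 with an estimated correlation), with Nrl (2.90 ± 0.14) and Samd7 (3.29 ± 0.19). Cone genes rose in 5 of 13 (adjusted p = 0.0087, 0.24 with an estimated correlation), with the cone arrestin Arr3 (2.07 ± 0.38). Glycolysis genes rose in 3 of 17 (adjusted p = 0.01, 0.57 with an estimated correlation, 0.13 by fry). Immediate early genes rose in 8 of 19 (adjusted p = 0.036, 0.17 with an estimated correlation), with Fosb (2.30 ± 0.45). Cell cycle genes fell in 30 of 37 (33 adjusted over the list alone; median -2.28, adjusted p = 1.5e-24, 0.17 with an estimated correlation), with Cdk1 (-3.17 ± 0.45) and Top2a (-2.96 ± 0.36). Progenitor and neurogenic genes fell in 14 of 22 (15 adjusted over the list alone; adjusted p = 2.1e-11, 0.17 with an estimated correlation), with Olig2 (-2.70 ± 0.34). The fetal and imprinted list moved down (adjusted p = 0.027, 0.48 with an estimated correlation, 0.12 by fry) with 3 falls and 1 rise. Bipolar, Muller glia, amacrine, ER folding and T, NK and myeloid lists were not called (adjusted p from 0.1 to 0.73), although Rlbp1 (3.02 ± 0.20) of Muller glia rose and Onecut1 (-2.65 ± 0.45) of horizontal cells fell. Counts were 613 up and 675 down among 11704; without P4 GFP+ CD73- replicate 1 the total went from 1288 to 809. Prdm1 did not pass the test (0.04 ± 0.12, adjusted p = 0.85).

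At P4, CD73+ cells carried more of the rod program than reporter-positive CD73- cells. Gngt1 (430.4 ± 28.7 against 50.4 ± 6.63 RPM, log2 3.07 ± 0.22), the rod transducin gamma chain, rose. So did Pax7 (3.28 ± 0.37), Impg1 (3.04 ± 0.22), Cnga1 (2.96 ± 0.21), Tdrd7 (2.94 ± 0.16) and Cacnb2 (2.94 ± 0.31). The 8 largest falls held microglial genes: C1qc (1.46 ± 0.939 against 46.5 ± 39.7 RPM, log2 -4.02 ± 0.51), Tyrobp (0.618 ± 0.126 against 21.6 ± 11.9 RPM, log2 -3.70 ± 0.46), C1qb (-3.55 ± 0.52), Ctss (-3.41 ± 0.44), Laptm5 (-3.27 ± 0.67), Csf1r (-3.09 ± 0.58) and Fcrls (-2.93 ± 0.55), next to Pcdhga10 (-3.04 ± 0.73). Laptm5 (-1.98) and Fcrls (-2.06) were not called without P4 GFP+ CD73- replicate 2, nor Pcdhga10 (-1.77) without P4 CD73+ replicate 1. The T, NK and myeloid list fell in 6 of 9 (8 adjusted over the list alone; adjusted p = 7.5e-08, 0.16 with an estimated correlation), so markers of myeloid cells moved with the CD73- sort. The largest adjusted p among the 14 genes was 0.012.

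Rod genes rose in 26 of 30 (median 2.17, adjusted p = 9.5e-42, 0.089 with an estimated correlation), with Pde6a (2.78 ± 0.28). Ribbon synapse genes rose in 4 of 16 (adjusted p = 3.9e-08, 0.16 with an estimated correlation), with Cacna1f (2.06 ± 0.21) and Slc17a7 (2.04 ± 0.25). Cilium genes rose in 5 of 30 (adjusted p = 2.9e-08, 0.16 with an estimated correlation), with Arl6 (1.57 ± 0.22). Glycolysis genes rose in 3 of 17 (adjusted p = 0.042, 0.61 with an estimated correlation, 0.19 by fry, 0.079 with quantile normalization), with Hk1 (2.00 ± 0.18), and the cone list moved up with 1 of 13 called (adjusted p = 0.038, 0.34 with an estimated correlation, 0.098 by fry). Progenitor and neurogenic genes fell in 6 of 22 (adjusted p = 0.0087, 0.55 with an estimated correlation, 0.11 by fry), with Atoh7 (-2.55 ± 0.34), Olig2 (-2.05 ± 0.34) and Neurod4 (-1.97 ± 0.14). Among the rest, Nr2e3 (1.46 ± 0.16) rose and Lhx4 (-2.16 ± 0.21), Onecut2 (-1.96 ± 0.29) and Meg3 (-1.39 ± 0.23) fell, but the lists of photoreceptor transcription factors, bipolar, amacrine, Muller glia, fetal, cell cycle, ER folding and immediate early genes were not called (adjusted p from 0.11 to 0.73). In total 402 genes rose and 284 fell, and 686 calls became 443 without P4 CD73+ replicate 1. Prdm1 was lower by less than the minimum fold change (-0.82 ± 0.12, adjusted p = 3.3e-04).

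Between P4 and P6 the CD73+ sort gained genes of bipolar cells. Grm6 (79.5 ± 15.1 against 0.250 ± 0.0204 RPM, log2 6.00 ± 0.53), the glutamate receptor of ON bipolar cells (Entrez ID 108072; chromosome 11, 50850369 to 50866208), Bhlhe23 (66.3 ± 2.97 against 2.59 ± 3.67 RPM, log2 4.76 ± 0.67), Vsx1 (44.9 ± 9.22 against 1.31 ± 1.81 RPM, log2 4.57 ± 0.58) and Trpm1 (24.2 ± 4.14 RPM in P6, listed at 0 in P4 CD73+), its channel, rose. Trnp1 (5.11 ± 0.48), Scgn (4.76 ± 0.55), Gabrr1 (4.36 ± 0.44) and Isl1 (4.21 ± 0.33) rose as well. Tmem92 (-3.64 ± 0.45), St14 (-3.59 ± 0.31), Top2a (-2.47 ± 0.36), Pbk (-2.44 ± 0.45), Lrrc48 (-2.44 ± 0.32), Mki67 (-2.19 ± 0.43), Ect2 (-2.15 ± 0.43) and Epha8 (-2.13 ± 0.29) fell. Pbk, Mki67 and Ect2 were not called without P4 CD73+ replicate 2 (-1.78, -1.55 and -1.67), P6 replicate 1 (-2.41, -2.10 and -2.38) or P6 replicate 2 (-2.48, -2.28 and -1.92). Across these 16 genes the adjusted p reached 0.01.

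Bipolar genes rose in 10 of 16 (12 adjusted over the list alone; median 1.60, adjusted p = 1.1e-22, 0.089 with an estimated correlation). Rod genes rose in 8 of 30 (9 adjusted over the list alone; median 0.69, adjusted p = 6.5e-13, 0.16 with an estimated correlation), with the exchanger Slc24a1 (2.79 ± 0.43) and Rcvrn (1.55 ± 0.18). Cell cycle genes fell in 14 of 37 (22 adjusted over the list alone; adjusted p = 3.4e-22, 0.17 with an estimated correlation). The progenitor list moved down with 1 of 22 members called (adjusted p = 1.1e-06, 0.29 with an estimated correlation, 0.14 by fry). So did the fetal list with 0 of 12 (adjusted p = 0.042, 0.52 with an estimated correlation, 0.26 by fry) and the immediate early list with 1 of 19 (adjusted p = 0.012, 0.16 with an estimated correlation). The ribbon synapse (adjusted p = 0.0018, 0.29 with an estimated correlation), cone (adjusted p = 0.043, 0.35 with an estimated correlation, 0.12 by fry), glycolysis (adjusted p = 0.027, 0.59 with an estimated correlation, 0.37 by fry) and ER folding lists (adjusted p = 0.042, 0.48 with an estimated correlation, 0.078 by fry, 0.053 with quantile normalization) moved up, with 1 rise each and, for cones, 1 fall. Photoreceptor transcription factors, Muller glia, amacrine, cilium and T, NK and myeloid lists were not called (adjusted p from 0.077 to 0.8; the medians of the transcription factor and amacrine lists were below 0 and their means above). In all 316 genes were called, 182 up and 134 down, but 143 without P4 CD73+ replicate 2, 139 without P6 replicate 1 and 115 without P6 replicate 2. Prdm1 was again under the minimum fold change (-0.86 ± 0.12, adjusted p = 7.5e-04).

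From P6 to P10 rod genes rose further while genes of progenitors and Muller glia fell. Gnat1 (2330.3 ± 907 against 72.6 ± 12.3 RPM, log2 4.94 ± 0.26), rod transducin, Drd4 (280.1 ± 139.7 against 2.43 ± 0.702 RPM, log2 6.28 ± 0.50), a dopamine receptor, and Opn1mw (63.0 ± 30.8 against 1.12 ± 0.488 RPM, log2 4.85 ± 0.49), the green cone opsin, rose. So did Guca1b (4.54 ± 0.36), Kcnj14 (4.34 ± 0.51), Kcng4 (4.22 ± 0.55), Slc24a1 (4.06 ± 0.43) and Cds1 (3.47 ± 0.40). Epha8 (2.71 ± 2.41 against 63.2 ± 0.363 RPM, log2 -4.28 ± 0.29), an ephrin receptor, Miat (14.3 ± 5.06 against 161 ± 67.6 RPM, log2 -3.38 ± 0.33) and Klhl33 (-4.32 ± 0.45) fell, as did Insm2 (-4.15 ± 0.24), Robo3 (-4.07 ± 0.21), Ece1 (-3.73 ± 0.23), Mmp14 (-3.43 ± 0.23) and Tead2 (-3.41 ± 0.23) (largest adjusted p of the 16: 7.4e-05). Rod genes rose in 21 of 30 (median 1.36, adjusted p = 4.7e-32, 0.089 with an estimated correlation). Ribbon synapse genes rose in 5 of 16 (adjusted p = 2.7e-06, 0.17 with an estimated correlation), with Cabp4 (2.58 ± 0.38). Bipolar genes rose in 7 of 16 with 1 down (adjusted p = 2.7e-05, 0.2 with an estimated correlation), with Car8 (2.99 ± 0.46) and Lrtm1 (2.95 ± 0.55). The cilium list moved up (adjusted p = 4.3e-07, 0.17 with an estimated correlation) with 1 member called.

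Progenitor and neurogenic genes fell in 16 of 22 (17 adjusted over the list alone; median -2.04, adjusted p = 9.9e-17, 0.16 with an estimated correlation), with Hes5 (-3.12 ± 0.23). Muller glia genes fell in 7 of 10 (adjusted p = 1.1e-06, 0.16 with an estimated correlation), with Sox9 (-2.49 ± 0.31). Amacrine, horizontal and ganglion cell genes fell in 7 of 15 (adjusted p = 0.042, 0.21 with an estimated correlation, 0.073 with quantile normalization), with Gad2 (-2.48 ± 0.34). Cell cycle genes fell in 20 of 37 (21 adjusted over the list alone; adjusted p = 1.8e-06, 0.48 with an estimated correlation, 0.069 by fry), with Mki67 (-2.92 ± 0.43). Fetal genes fell in 5 of 12 (adjusted p = 0.027, 0.48 with an estimated correlation, 0.051 by fry), with Igf2bp3 (-1.78 ± 0.22). Gngt2 (-3.15 ± 0.21), the cone transducin gamma chain, fell while Pde6c (1.81 ± 0.30) rose. The cone list was not called, nor were the lists of photoreceptor transcription factors, glycolysis, T, NK and myeloid, ER folding and immediate early genes (adjusted p from 0.1 to 1; the ER median was above 0 and the mean below). Counts were 390 up and 892 down, with a median shift of -0.13; rises were 30.4% of the calls, 41.5% with median-of-ratios scaling and 46.4% with quantile normalization. The total of 1282 became 776 without P10 replicate 2. The change of Prdm1 was under the minimum (-0.89 ± 0.12, adjusted p = 1.2e-04).

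Over the whole retinal series (P10 against P0), Gnat1 (2330.3 ± 907 against 1.50 ± 0.517 RPM, log2 9.83 ± 0.26), Cnga1 (9.19 ± 0.21) and Gngt1 (8.94 ± 0.22) were among the largest rises. Foxn4 (-7.90 ± 0.35), Olig2 (-7.72 ± 0.34), Mki67 (-7.44 ± 0.43) and Neurog2 (-7.44 ± 0.29) were among the largest falls (largest adjusted p of the 7: 7.0e-10). All 30 rod genes rose (median 6.81, adjusted p = 1.4e-31, 0.089 with an estimated correlation) and all 37 cell cycle genes fell (median -4.09, adjusted p = 1.5e-17, 0.2 with an estimated correlation). Ribbon synapse genes rose in 14 of 16 (adjusted p = 4.0e-12, 0.12 with an estimated correlation). Cilium genes rose in 21 of 30 (1.3e-09, 0.16) and bipolar genes in 14 of 16 (3.8e-08, 0.16). Photoreceptor transcription factors rose in 7 of 11 with 2 down (0.0087, 0.28), with Esrrb (7.51 ± 0.51) among the rises. Cone genes rose in 8 of 13 with 1 down (adjusted p = 0.0014, 0.17 with an estimated correlation). Glycolysis genes rose in 7 of 17 (adjusted p = 3.8e-04, 0.47 with an estimated correlation), with Hk1 (4.13 ± 0.18). Progenitor genes fell in 21 of 22 (adjusted p = 2.3e-14, 0.16 with an estimated correlation). Muller glia, amacrine, fetal, T, NK and myeloid, ER folding and immediate early lists were not called (adjusted p from 0.11 to 0.75; the immediate early median was below 0 and the mean above). Prdm1 fell (-2.53 ± 0.12) and Nt5e rose (4.89 ± 0.27) among 1849 rises and 2357 falls.

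**Figure D4:**
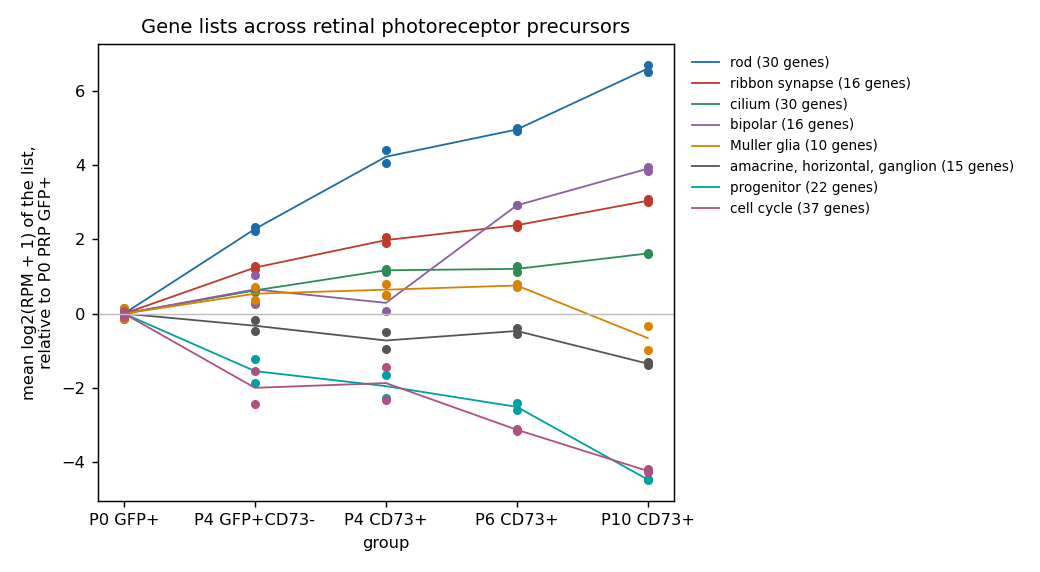
Mean log2(RPM + 1) of gene lists in retinal photoreceptor precursors, relative to P0. Each dot is 1 library and lines join group means.

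The 4 reporter-positive populations (d2 PGCLC, E16.5 intestine, P0 retina and PB) were each set apart by genes of their tissue, but not these alone. Tissue, age, strain and culture differ between them together with lineage. A gene counted as enriched when its change over each of the other 3 passed the test, and the smallest of the 3 log2 fold changes follows each mean, except where the other 3 were listed at 0. PGCLC were marked by T (1376 ± 196 RPM, 9.68), the mesoderm factor brachyury (Entrez ID 20997; chromosome 17, 8434423 to 8442496), Tdgf1 (690.0 ± 0.339 RPM, 8.84), Msgn1 (275 ± 33.6 RPM) and Pou5f1 (460.2 ± 26.4 RPM, 7.27), the pluripotency factor OCT4. They were also marked by Nanog (149 ± 3.38 RPM, 7.05), Igfbp3 (465 ± 84.1 RPM, 7.86), L1td1 (248 RPM, 7.07), Rspo3 (127 ± 8.16 RPM), Trh (165 ± 3.57 RPM, 6.97) and Msx1as (172 ± 17.2 RPM, 6.87). The E16.5 intestine was marked by Fabp1 (4713 ± 723 RPM, 11.28) and Fabp2 (6592 ± 4.45 RPM, 10.77), fatty acid carriers, Apoa4 (4935 ± 57.5 RPM, 10.50) and Apoa1 (3961 ± 289 RPM, 10.46). Further genes of this set were Lgals4 (4289 ± 125 RPM, 9.68), Lgals2 (1122 ± 56.6 RPM, 9.67), Muc13 (1426 ± 75.0 RPM, 9.58), Dmbt1 (1097 ± 138 RPM, 9.50) and Cps1 (1422 ± 116 RPM, 9.47). The P0 retina was marked by Miat (1253 ± 175 RPM, 9.87), Neurod4 (1279 ± 90.7 RPM, 9.30), Neurog2 (528 ± 0.544 RPM), Six3 (562 ± 53.2 RPM, 8.37) and Otx2 (1562 ± 163 RPM, 8.36), the factor of photoreceptor fate. It also had Rorb (716 ± 118 RPM, 8.36), Rax (424 ± 84.9 RPM, 8.24), Atoh7 (289.7 ± 29.3 RPM), Neurod1 (1717 ± 192 RPM, 8.02) and Dkk3 (568 ± 72.3 RPM, 7.97). PB were marked by Igj (13123 ± 449.6 RPM, 10.20), Ly6a (4092 ± 737 RPM, 9.67), Cd52 (2342 ± 375 RPM, 8.42) and Pou2af1 (1591 ± 60.2 RPM, 8.34), a coactivator of immunoglobulin genes. Also enriched were Cd79a (962 ± 27.1 RPM, 8.23), Ly6c2 (477 ± 30.9 RPM, 8.17), Srgn (902 ± 139.9 RPM, 7.97), Cytip (359 ± 25.2 RPM, 7.71), Cd74 (966 ± 127 RPM, 7.70) and Glipr1 (1021 ± 217 RPM, 7.68). The largest adjusted p among these 39 was 4.0e-06.

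PGCLC, set against the mean of the other 3, were higher in 18 of 18 genes of mesoderm and BMP response (median 5.11, adjusted p = 1.2e-10, 0.09 with an estimated correlation). They were higher in 16 of 17 of naive pluripotency (3.6e-08, 0.12) and 8 of 9 of germ cell specification (0.004, 0.14). In the cell cycle 20 of 37 were higher (2.9e-06, 0.16). PGCLC were cultured with BMP4 and BMP8A (500 ng/mL each), so BMP response and lineage cannot be told apart. Prdm14 (19.7 ± 5.65 RPM, 4.05) and Ifitm3 (378 ± 25.0 RPM, 3.96) of germ cell specification were enriched, whereas the primed epiblast list was not called (adjusted p = 0.18). E16.5 cells were higher in 25 of 27 enterocyte genes (median 7.69, adjusted p = 3.9e-16, 0.09 with an estimated correlation). The same held for 10 of 12 suckling-period (5.5e-07, 0.09), 8 of 8 goblet (1.3e-05, 0.09) and 6 of 6 Paneth genes (1.4e-04, 0.2). Of the latter, Reg3b (594 ± 588 RPM) and Reg1 (171 ± 198 RPM) had a wide spread between libraries. In all 4 groups, a gene could pass the filter of 5 RPM in 2 samples through 1 group alone. The shares of tissue genes that were higher were therefore partly set by the filter. In the intestinal fit 11 goblet and 13 Paneth genes were tested. P0 cells were higher in 21 of 22 progenitor and neurogenic genes (median 5.84, adjusted p = 6.1e-07, 0.11 with an estimated correlation) and 9 of 9 cone genes (adjusted p = 0.0012, 0.13 with an estimated correlation). They were also higher in 13 of 15 rod (0.0056, 0.26) and 28 of 29 cilium genes (7.7e-04, 0.2). This also held for 11 of 12 ribbon synapse (0.0014, 0.16) and 9 of 10 Muller glia genes (0.0076, 0.2).

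PB were higher in 18 of 19 plasma cell genes (median 5.64, adjusted p = 1.3e-28, 0.035 with an estimated correlation) and 31 of 38 ER folding genes (adjusted p = 3.2e-38, 0.061 with an estimated correlation). PB were also higher in 17 of 19 B cell identity genes (adjusted p = 1.3e-20, 0.09 with an estimated correlation), all 10 MHC class II genes (adjusted p = 6.8e-16, 0.15 with an estimated correlation) and 13 of 16 MHC class I and interferon genes (adjusted p = 2.3e-17, 0.09 with an estimated correlation). P0 cells had the reverse in MHC class I, with all 16 lower (median -3.26, adjusted p = 1.6e-12, 0.09 with an estimated correlation). The cell cycle list was called up in PB with a median of -0.05 (adjusted p = 2.2e-04, 0.2 with an estimated correlation, 0.63 by fry), so its median and test differed in sign. The list of mesenchyme, endothelium and enteric neuron markers was not called in any of the 4 (lowest adjusted p = 0.35).

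Markers of other cells were also measured. All 4 erythroid genes were enriched in E16.5 cells, including Hba-a1 (69.0 ± 31.8 RPM, 3.19) and Hbb-b1 (45.8 ± 26.2 RPM, 3.47). In P0 cells 5 of 9 T, NK and myeloid markers were enriched, including C1qa (15.7 ± 7.79 RPM) and Tyrobp (11.3 ± 1.53 RPM, 3.05). Enrichment also reached 2 of 3 later germ cell genes and 2 of 4 adult-type enterocyte genes in E16.5 cells, and 2 of 4 endothelial and pericyte genes in P0 cells; these lists had too few tested members for a list test. In all, 754 genes were enriched in PGCLC, 1435 in E16.5, 2471 in P0 and 581 in PB among 12578 tested. With median-of-ratios scaling the P0 set held 1515 genes and the PB set 990. Leaving out replicate 1 or 2 of the group itself gave 217 or 250 in PGCLC, 664 or 667 in E16.5, 1140 or 1267 in P0 and 249 or 243 in PB.

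Changes linked to the reporter were compared between lineages, with PB minus Blast, E16.5 minus P14 and P0 minus P10 the population with more Prdm1 first in each. Higher in both B lineage and intestine were Trf (3.08 and 3.62), transferrin (Entrez ID 22041; chromosome 9, 103208876 to 103230286), Slc46a3 (2.60 and 2.71), Cd36 (2.54 and 3.15) and Dusp14 (3.07 and 2.49). Lower in both were Atf3 (-3.53 and -3.71), Lrmp (-3.49 and -3.49), Vdr (-3.25 and -3.70) and Klf2 (-3.14 and -2.79). B lineage and retina shared rises of Cd24a (5.30 and 2.55), Prdm1 (5.80 and 2.53), Rab3d (2.60 and 2.51) and Ptgr1 (2.34 and 2.37). They shared falls of Tmem229b (-4.68 and -5.26), Grm6 (-4.13 and -6.42), Dhrs3 (-3.83 and -4.52) and Ablim1 (-3.52 and -5.69). Intestine and retina shared rises of Igf2bp1 (3.39 and 4.25), Meg3 (3.98 and 3.35), Emid1 (3.27 and 4.18) and Cmtm8 (3.67 and 3.22). Shared falls were Tph1 (-3.98 and -3.54), Scgn (-3.52 and -5.88), Hspa1a (-3.26 and -4.73), a heat shock gene with a near-identical paralog, and Lass4 (-3.15 and -3.26).

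Of 8152 genes tested in all 3 lineages, 12 were higher in each (5.43 expected from the product of the shares), among them Ftl1, Vat1, Gpx3, Faah and Cxxc5. Prdm1 was also among the 12, a direction set in advance by the order of the groups. A further 18 were lower in each (19.5 expected), among them Tmem229b, Atf3, Ptpla, Car2, Casz1 and Nt5e, the gene of the CD73 gate in retina. Overlaps by pair were tested with Fisher's exact test, adjusted over 12 tests by Benjamini-Hochberg. Genes are not independent replicates, so these p-values describe the lists. B lineage and intestine shared 80 rises (37.7 expected, adjusted p = 2.4e-10) and 224 falls (221 expected, 0.83). B lineage and retina shared 100 rises (87.4 expected, adjusted p = 0.19) and 274 falls (289 expected, 0.34). Intestine and retina shared 157 rises (143 expected, adjusted p = 0.23) and 111 falls (94.7 expected, 0.11).

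Opposite changes passed the test in 4 of 6 directions. Between intestine and retina, 399 genes were lower in E16.5 than P14 and higher in P0 than P10 (153 expected, adjusted p = 4.0e-93) and 146 the other way (88.1 expected, 6.6e-10). For B lineage and retina, 94 genes were higher in PB and lower in P0 (54.8 expected, adjusted p = 2.5e-07) and 497 the other way (460.1 expected, 0.05). For B lineage and intestine these were 62 (42.1 expected, adjusted p = 0.0038) and 189 (198 expected, 0.46). Genes that moved the same way in at least 2 lineages numbered 886, of which 313 were higher and 573 lower in the population with more Prdm1. These overlaps used the values as deposited, with 657 rises and 3051 falls from Blast to PB. Only 36.5% of those falls were still called after median-of-ratios scaling, so the B-lineage falls used here depend on scaling. The contrasts of intestine and retina also differ in age and gate, so the shared genes are a description of these populations.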

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

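All tests of explanations below were chosen only after the results were seen; the differences between lineages were planned.

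These 12 genes stood out because the changes linked to the reporter went opposite ways in 2 lineages, with the difference tested in a limma fit of all 26 samples. Between B lineage and intestine (PB minus Blast against E16.5 minus P14) the differences in log2 fold change were 8.26 for Kcnn4, -7.95 for Lcp1, 7.34 for Cd24a and -7.32 for Kynu. Between B lineage and retina (PB minus Blast against P0 minus P10) they were 13.08 for Igj, -8.24 for Pkib, -7.91 for Fam64a and -7.75 for Gpr56. Between intestine and retina (E16.5 minus P14 against P0 minus P10) they were 11.41 for Igf2, -10.89 for Fgf15, -10.11 for Pbk and -9.10 for Neil3. The genes were picked for calls in opposite directions, so this test added little: all 251, 591 and 545 such genes of the 3 pairs passed it. Igj in retina rose from 2.94 and 8.38 RPM at P0 to 31.2 and 43.7 at P10. The P10 values were low beside B cells, prePB and PB but above Blast (14.98 and 4.623 RPM). The log2 ratio of Igj to Ighm, relative to the B-lineage libraries together, was 1.097 and 0.6329 at P0. At P10 it was 2.581 and 1.975, above the highest B-lineage library (1.18, a B cell library). These ratios argue against carry-over from the B-lineage libraries as the whole source of Igj at P10, if the Ighm line is placed correctly. Resident B-lineage cells were not excluded.

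Ighm stood out because it lies in lines left out of the comparisons, yet reached 149 RPM in an intestinal library (P3 replicate 2) and 91.5 RPM in a retinal library (P10 replicate 2), while it was 0 in d2 PGCLC replicate 2, the only PGCLC library with a value in that line. Carry-over of RNA or reads from the B-lineage libraries is a candidate explanation: relative to Ighm, 16 B cell identity genes lay at a median log2 distance of 0.379 in intestine and 0.567 in retina from their ratio over all 8 B-lineage libraries. The quartiles ran from -0.283 to 2.63 in intestine and 0.130 to 1.77 in retina. Against single groups the medians were 2.16 and 2.62 for prePB, -3.10 and -3.14 for B cells, -3.24 and -3.39 for Blast and 5.15 and 5.27 for PB. B-lineage cells of the tissues cannot be told apart from this source, since Ighm was down to 0.0206% of the B-lineage level in 1 library and a mix of resident cells could have the same profile. The intestinal sorts were EpCAM+, which argues against such cells without excluding a few in the sort. The reporter-negative gate at P3 and P14 would not remove cells with as little Prdm1 as splenic B cells or blasts (9.83 and 2.81 RPM). The line of Ighm is among those whose position is less certain (23.0% of low values whole after the move).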

How the results depend on the processing

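The alternatives were set before the data were examined, except setting the moved lines back, which was chosen after seeing the data and left the calls of all 616 named gene values and 277 list tests as they were. The planned count tests (edgeR and DESeq2) were not run, because the signal held fractions of reads. No called result was called in the opposite direction by an alternative, but for the cell cycle list in PB, called up by camera, fry pointed down without a call (adjusted p = 0.63). Of the 165 list calls, fry ended 17, a filter at 20 RPM 11, 1 fit of all samples 9, quantile normalization 8, no filter 7, median-of-ratios scaling 6 and a pseudocount of 0.5 RPM 5. Without a minimum fold change, calls numbered 5098 for Blast against B cell, 1865 for prePB against Blast, 2724 for PB against prePB, 5647 for PB against Blast, 3890 for P3 against E16.5, 908 for P14 against P3, 4093 for P14 against E16.5, 2556 for P4 GFP+ CD73- against P0, 1327 for P4 CD73+ against CD73-, 500 for P6 against P4 CD73+, 2404 for P10 against P6 and 6502 for P10 against P0, and 2464 genes moved the same way in at least 2 lineages; more calls follow from this setting by construction. With a pseudocount of 5 RPM, which shrinks folds of low genes by construction, there were 655 for prePB against Blast, 655 for PB against prePB, 817 for P10 against P6 and 470 shared between lineages. With no filter on low values there were 664 for prePB against Blast, 143 for P14 against P3 and 111 for P6 against P4 CD73+. With a filter at 20 RPM there were 1376 for P3 against E16.5, 1510 for P14 against E16.5 and 478 shared. Median-of-ratios scaling gave 805 for PB against prePB (531 of them shared with the values as deposited), 2384 for PB against Blast (1770 shared), and 1515 and 990 genes enriched in P0 and PB; quantile normalization gave 688, 2258, 1431 and 979. An estimated correlation left 17 of 165 list calls. For these last 3 settings the cause was not tested. With P3 and P6 as the late stage, 711 genes moved the same way in at least 2 lineages (521 shared). With prePB for PB, enriched genes numbered 643 in PGCLC, 1401 in E16.5, 2397 in P0 and 640.0 in prePB, and with P4 GFP+ CD73- for P0 they numbered 943, 1394, 2857 (in P4) and 581.

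Leaving out 1 library at a time, with the lone sample assumed to vary like the other groups, moved some counts over 1.5 times. P14 against P3 gave 269 to 434 (269 without P3 replicate 1, 283 without P3 replicate 2, 278 without P14 replicate 1). P4 GFP+ CD73- against P0 gave 809 (without P4 GFP+ CD73- replicate 1) to 1276, and P4 CD73+ against CD73- gave 443 (without P4 CD73+ replicate 1) to 706. P6 against P4 CD73+ gave 115 to 278 (143 without P4 CD73+ replicate 2, 139 and 115 without P6 replicates 1 and 2), and P10 against P6 gave 776 (without P10 replicate 2) to 1096. Enriched genes ranged from 217 to 734 in PGCLC, 664 to 1426 in E16.5, 1140 to 2436 in P0 and 243 to 582 in PB, lowest without a replicate of the group itself. Counts of the other 7 comparisons, the overlap (831 to 896) and list calls (148 to 167) stayed within 1.5 times. Of 595 called named values, 98 lost their call without 1 library. Named gene values lost their call in 82 of 616 cases without a filter, 41 with a pseudocount of 5 RPM, 24 with median-of-ratios scaling and 28 with quantile normalization.

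The replicate number of the labels was not taken as a pairing, since no label states a shared animal, culture or day. Correlations of replicate differences between groups ran from -0.0541 to 0.284. Those above 0.1 were all between sorts of the same age or the same kind of culture. They were 0.284 for P4 GFP+ CD73- with P4 CD73+, 0.196 for Blast with prePB and 0.127 for prePB with PB, against 0.0724 for Blast with PB. Shared preparations of these groups are therefore possible. The replicate block used 1 term over all groups of a lineage and could not model single pairs, so it does not settle the pairing. With a replicate block, calls numbered 3406 for Blast against B cell, 1079 for prePB against Blast, 1353 for PB against prePB and 704 for P4 CD73+ against CD73-, the pair with the highest correlation, and all 616 named gene calls were the same. Of the 277 list tests 272 had the same call, 1 was lost (fetal genes, P6 against P4 CD73+, adjusted p = 0.054) and 4 gained: immediate early genes in Blast against B cell (0.036), MHC class II in prePB against Blast (0.047), glycolysis in E16.5 (0.049) and T, NK and myeloid markers in P0 (0.046). Depth limits values near 1 RPM most in the shallowest libraries, since the smallest step reached 0.583 RPM.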

Other observations

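All tests of explanations below were chosen only after the results were seen.

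Most called genes fell from Blast to PB (3051 of 3708). The share of reads left to genes other than immunoglobulins fell by 0.54 log2 (-0.5439) between these groups, close to the median gene at -0.64, so a growing immunoglobulin share may account for the general shift. After median-of-ratios scaling, which takes out a general shift of any cause, 1271 genes rose and 1113 fell, so the excess of falls was gone. The list of genes known to be repressed by BLIMP1 had a median of -3.13 after this scaling, beyond the general shift. Repression by BLIMP1 as the cause is left as a hypothesis, as Prdm1 rose in the same cells and no sample without BLIMP1 was compared.

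Bipolar genes rose in the CD73+ retinal sort from P4 to P6. A lower share of rod precursors with every other cell type raised alike was argued against but not excluded. The medians ± standard error were 0.135 ± 0.239 for Muller glia and -0.172 ± 0.4525 for amacrine genes, against 1.60 ± 0.571 for bipolar genes. These standard errors were taken over the genes of each list, which are not independent replicates. Bipolar cells within the sort, with 62.5% of the list up, and bipolar genes switched on in CD73+ precursors with less Prdm1 (-0.86) cannot be told apart, because the libraries are bulk and both predict the same rise, and the change of Prdm1 did not reach the fall of at least 1 set for the second; single-cell measurement would be needed.

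Some zeros were not matched by the other replicate. Igkc was 0 in PB replicate 2 and 141198 RPM in replicate 1, as were Igk, Igkv1-117 and Igkv1-110 (14632, 59.3 and 56.3 RPM in replicate 1), all in lines left out of the comparisons. Rasgrf2 was 0 in P4 CD73+ replicate 2 and 157 RPM in replicate 1. These zeros were not read as absent expression.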
